A study of Mus musculus with 8 samples.

How the data were processed

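Bulk RNA-seq was measured in 3 libraries of mESCs and 3 of mCMG-TBLCs, and single-cell RNA-seq in TBLC-blastoids. Groups and replicate numbers came from the sample titles. The bulk values are estimated counts per gene symbol that the authors deposited in 1 table per group. Per the submitters' processing notes, Trim Galore, STAR, RSEM, RMA, Seurat and Scanpy were used, with no versions, and the genome build was mm10. The notes do not tie a tool to a table, and the annotation is not given in the sources used here. Some deposited estimated counts have decimals, 20.7% to 22.1% of the values above 0 in each library. The single-cell values are UMI counts in 1 deposited table of 33089 genes and 2790 cells. Its cells had at least 3010 genes and at most 10.0% mitochondrial UMIs, so that they appear to have been filtered before deposit. The labels name 10x Genomics for these libraries. All value columns were used.

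The depth of the bulk libraries was 38032770, 37653376 and 39067921 estimated counts for mCMG-TBLC replicates 1 to 3 and 21867778, 26684232 and 16100872 for mESC replicates 1 to 3. The 20 genes with the most counts took 10.8% ± 0.266 of counts in mCMG-TBLCs and 18.3% ± 1.11 in mESCs. Correlations of log CPM were 0.987 to 0.992 within mCMG-TBLCs, 0.979 to 0.990 within mESCs and 0.893 to 0.910 between the groups. The cells of barcode suffix 0 (1262 cells) had a median of 64041 UMIs and those of suffix 1 (1528 cells) of 45977. Intervals and floors cover counting error only.

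Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, a quasi-likelihood fit with the group as the only term, and Benjamini-Hochberg adjustment over 16453 of 54488 genes, with a threshold of 0.05. CPM in the text are scaled by TMM factors. Standard errors were taken as the size of the log2 fold change over the square root of F. For a gene at 0 in all libraries of a group, the fold is a lower bound against 3 counts over that group. With 1 to 3 counts in a group, the ratio of pooled counts per effective library size is given with an exact binomial 95% interval, which covers counting error only. The common biological coefficient of variation was 14.2%. On simulated counts for this comparison (16093 genes, 200 of them changed), 77 of 100 genes changed 2-fold and 98 of 100 changed 4-fold were recovered. False calls were 17, or 8.85% of calls, above the nominal rate. The 200 genes were changed equally up and down, whereas 9780 of 16453 genes were called in the real comparison. These rates therefore need not hold for the real data. With no gene changed, 0 genes by edgeR (799 at an unadjusted p under 0.05) and 0 of 26 lists by camera were called. The single-cell steps were tested on cells simulated from 3 cluster profiles, all 300, 200 and 60 of which were named as simulated. The naming rule had been settled on the clusters themselves, so this result does not test whether the names are right.

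The 26 gene lists cover two-cell stage, naive and core pluripotency, formative and primed pluripotency, gastrulation germ layers, trophectoderm with polar and mural subsets, primitive endoderm, p53 targets, spliceosome, DNA methylation enzymes, oocyte and maternal, germline, fibroblast feeder, stress, cholesterol synthesis, glycolysis, cytosolic ribosomal proteins, mitochondrially encoded, DNA replication, mitosis, histones, immediate early, imprinted, sex chromosome, and interferon genes. Each was tested with camera of limma 3.58.1 with a preset correlation of 0.01, with camera with an estimated correlation and with fry, adjusted over the lists. Lists, cell type markers, main tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule takes the 6 largest rises and 6 largest falls among called genes without overlap between groups, at 5 CPM or more in the higher group and with a symbol that is not a clone or predicted name, then 20 fixed genes, then up to 3 called members per list at 5 CPM or more. For single cells it takes 12 fixed markers, and other genes named there were picked after their values were seen. Its part on called members of lists in single cells was not used, since no test was made there.

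Gene positions, exon numbers, exon lengths and GC content came from GENCODE vM21 (mm10), which matched 97.1% of the bulk gene symbols. Length and GC content were known for 98.8% of tested genes.

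Single cells were analysed with scanpy 1.11.5. The filter (at least 3000 genes, at most 10% mitochondrial UMIs) removed 0 cells. Its thresholds, those of the stricter filter (4000 genes) and the thinning depth (20000 UMIs) were set after the cells had been seen. Scrublet, run per barcode suffix, marked 2 cells (0.0717%), which were left out. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes less those of 9 lists left 1922, from which 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6 gave 11 clusters, numbered by size. A cluster was named for the class with most markers among its top 50 genes by fold against the median of the other clusters (at least 0.3 UMIs per 10000, pseudocount 0.1), if it had at least 3 markers and at least 2 more than the next class. This naming rule was settled after the clusters had been seen and after 3 other forms of it had been tried, so those forms are given as alternatives. Shares have exact binomial and sums of UMIs exact Poisson 95% intervals.

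For bulk counts, the alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, each library left out, the replicate number as a block, leaving out mitochondrial and the 20 highest genes, DESeq2 1.42.0, limma-voom and a test against a 1.5-fold change. Added after seeing the data were a loess trend over length and GC content in 2 forms and leaving out 2 libraries in doubt, mCMG-TBLC replicate 2 (highest fibroblast transcripts) and mESC replicate 3 (fewest counts). For single cells, resolution, variable genes, components, the cell filter, doublets, seeds, naming, the UMI threshold and depth were varied. One form of naming, added after seeing the data, left a cluster unnamed if its 10 leading genes held more markers of another class than of its own. Tests and alternatives that need cells to be tied to a library were planned but not run, because no label ties a barcode suffix to a library.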

Results

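Bulk RNA-seq was done on 2 groups of 3 libraries each: mouse embryonic stem cells (mESCs) and mCMG-TBLCs. The latter are blastomere-like cells that the submitters describe as totipotent. They were obtained by growing mCMG ESCs on feeder cells in ES medium that held 2.5 nM PlaB (pladienolide B, an inhibitor of the splicing factor SF3B1) for more than 6 passages. Blastocyst-like structures made from such cells, TBLC-blastoids, were profiled by droplet single-cell RNA-seq in 2 libraries per the labels. The mCMG-TBLC libraries held 37653376 to 39067921 estimated counts and the mESC libraries 16100872 to 26684232. The single-cell table held 2790 cells with 7288 to 171798 unique molecular identifiers (UMIs) per cell and a median of 52918.

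The comparison of mCMG-TBLCs with mESCs asked how gene expression differs between these 2 groups. Genes of the two-cell embryo stood far above their mESC level in mCMG-TBLCs. Zscan4c, of a gene family active in two-cell embryos, was at 660 ± 164 CPM in mCMG-TBLCs and 4.71 ± 0.380 CPM in mESCs (SD, n = 3 each), 141-fold higher. Of the core pluripotency factors, Pou5f1 was 1.48-fold and Nanog 1.82-fold higher, whereas Sox2 was 1.61-fold lower (edgeR adjusted p = 0.000344, 5.5e-05 and 0.000166). The DNA methyltransferase gene Dnmt3b was 3.43-fold lower, and 14 of 19 genes of formative and primed pluripotency fell.

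Of 16453 genes tested with edgeR, 5105 were higher and 4675 lower in mCMG-TBLCs at an adjusted p under 0.05, 9780 in all. At least a 2-fold change was seen for 2736 of the higher and 1751 of the lower genes. The libraries of the 2 groups did not overlap for 10891 genes, 66.2% of those tested, where chance gives 10%. Against a minimum fold of 1.5, 4765 genes passed, and of the genes named here Pou5f1, Sox2, Mdm2, Dnmt3l, Sox1, Pmvk, Hist1h2bc, Ddx58 and Stat2 did not. After a trend over transcript length and GC content was taken off each library without centring, 4034 genes were higher and 5815 lower, so that 41.0% of the changed genes were higher, beside 52.2% without it and 53.9% with the trend centred. That uncentred trend shifted the median log2 fold change by -0.17. The groups came from separate tables and differed in depth, so a batch and the group cannot be told apart. PlaB and any difference in cell line or culture also go with the group. They cannot be told apart from the blastomere-like state either. No label says that replicates came from separate cultures, and p-values therefore measure only the spread between these libraries, which may be technical.

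**Figure D1:**
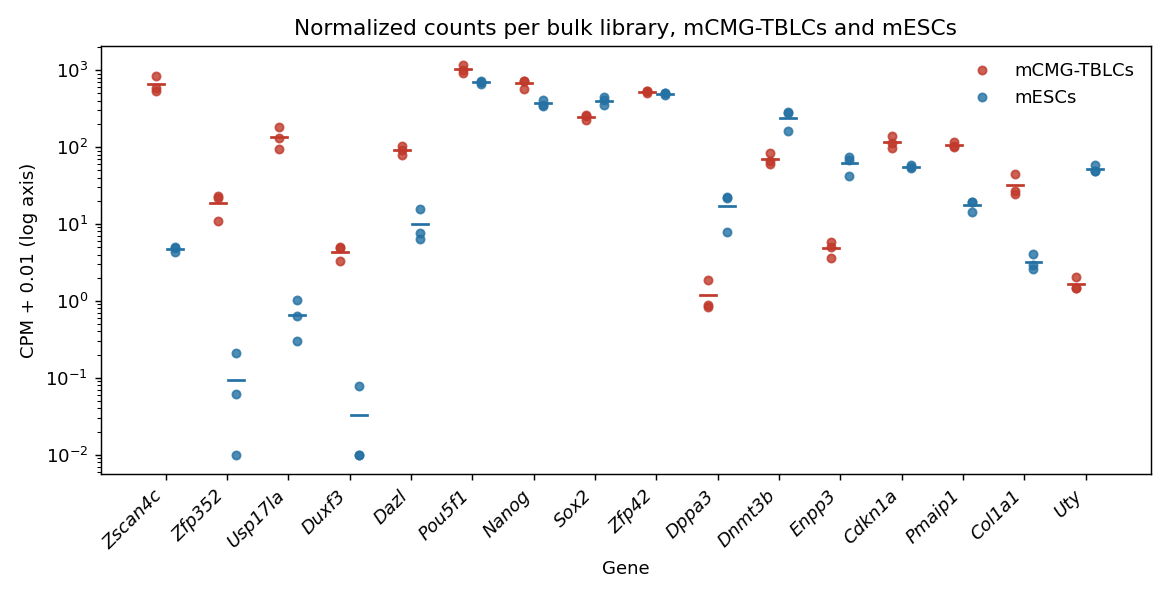
Normalized counts of 16 genes in each of the 6 bulk libraries. The vertical axis is CPM plus 0.01 on a log scale, points are libraries (red, mCMG-TBLCs; blue, mESCs) and lines are group means. Zscan4c, Zfp352, Usp17la and Duxf3 are higher in mCMG-TBLCs, Pou5f1 and Zfp42 differ by less than 1.5-fold, and Dppa3, Enpp3 and Uty are lower.

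The two-cell stage list moved almost as a whole. Of its 42 members tested, 40 rose and 2 (Zfp750 and AU018091) fell, the same counts as when adjusted over the list alone. The median log2 fold change was 7.63, or 7.46 with genes at 0 in a group set to their bound. Zfp352, a zinc finger gene of the two-cell embryo, was at 18.5 ± 6.75 CPM in mCMG-TBLCs and 0.0848 ± 0.106 CPM in mESCs, with a log2 fold change of 7.99 ± 0.56 (SE) and an edgeR adjusted p of 1.43e-06. The log2 fold change of Zfp352 was 7.26 without mESC replicate 2 and 9.44 without mESC replicate 3. Duxf3 (Dux), which encodes a transcription factor that activates two-cell stage genes, was at 4.36 ± 0.961 CPM in mCMG-TBLCs and had 1 count in the mESC libraries together (edgeR adjusted p = 2.9e-06). The ratio of its pooled counts was 256.5 with an exact 95% counting interval of 45.8 to 10150, and 149.6 without mESC replicate 2. Without mESC replicate 3, which held the single count, Duxf3 was at least 63.8-fold higher. Tcstv3, Tdpoz3 and B020004J07Rik had no counts in any mESC library and were at least 207-fold, 175-fold and 189-fold higher, against a floor of 3 counts over the group. Without mESC replicate 2, the deepest of its group, these bounds were 121-fold, 102-fold and 110.0-fold. Members of these families share near-identical sequence, so single members such as Usp17lb (974-fold) and Usp17la (230-fold) are uncertain and family sums are safer. Usp17ld had 3 counts in mESCs, and its ratio of pooled counts was 950.1 (325 to 4608). The 6 Zscan4 genes together were at 2908 ± 728 CPM against 15.96 ± 2.79 CPM, 182-fold higher, and the 5 Usp17l genes at 602 ± 166 CPM against 2.07 ± 1.08 CPM, 292-fold higher. The 5 Tdpoz genes were at 18.5 ± 4.72 CPM against 0.0533 ± 0.0135 CPM, which is 3 counts, with a ratio of pooled counts of 359.9 (123.0 to 1746). The Tcstv genes were at 11.4 ± 3.01 CPM against 0, at least 222-fold higher, or 129.5-fold without mESC replicate 2. The list was called by camera with a preset correlation of 0.01 (adjusted p = 8.3e-65). Its adjusted p was 0.135 with an estimated correlation, and none of the 12 lists that camera called was called with an estimated correlation.

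Of the germline list, 21 of 33 members rose and 2 fell (22 and 2 when adjusted over the list alone), with a median log2 fold change of 1.06. Dazl, an RNA-binding protein of germ cells, rose 9.40-fold to 90.8 ± 12.6 CPM, Slc25a31 rose 9.94-fold and the tubulin gene Tuba3b 34.4-fold. Camera called the list (adjusted p = 0.000711), with an adjusted p = 0.542 with an estimated correlation. Of 36 oocyte and maternal genes, only 11 were tested, since 2 were absent and the rest did not pass the count filter. Of these 11, 7 rose and 2 fell, with a median of 1.24. Khdc3 and Tle6, of the subcortical maternal complex of the oocyte, rose 2.65-fold and 2.37-fold. Dppa3, a maternal factor that is also a marker of naive cells, fell 14.5-fold, from 17.2 ± 8.13 to 1.19 ± 0.584 CPM. This list was not called (camera adjusted p = 0.184).

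Pluripotency genes went both ways. In the naive and core list, 12 of 32 members rose, 14 fell and 6 did not pass, with a median log2 fold change of -0.06 that was 0.01 with upper-quartile scaling. Nanog did not pass with the uncentred trend over length and GC content taken off (log2 fold change 0.22). Fbxo15 rose 3.21-fold and Lefty1 4.84-fold, and Utf1 fell 6.70-fold. Without mESC replicate 2 the log2 fold change of Lefty1 was 2.88, beside 2.28 with it. Zfp42 (Rex1) was at 525 ± 19.3 CPM against 493 ± 10.4 CPM and did not pass (edgeR adjusted p = 0.263). It was called higher with upper-quartile scaling, at 0.16 on the log2 scale, and lower after the trend was taken off, at -0.47 centred and -0.65 uncentred. The list was not called by camera (adjusted p = 0.329). After the trend was taken off the list was called lower, with a median of -0.21 centred and -0.40 uncentred. Of 19 formative and primed genes, 14 fell and 3 (Sox3, Nodal and Lefty2) rose, with a median of -1.47. Enpp3 fell 12.97-fold to 4.79 ± 1.15 CPM, Lef1, a transcription factor of WNT signalling, fell 5.03-fold and Zic2 fell 4.63-fold. Camera called it lower (adjusted p = 0.000711), with an adjusted p = 0.415 with an estimated correlation. Among 13 gastrulation germ layer genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone), the list was not called (camera adjusted p = 0.612), and its median was -0.90, or -0.12 with a 1 CPM filter. Pax6 fell 9.99-fold and Sox1 1.86-fold, and Eomes rose 3.55-fold. Without 2 libraries in doubt (mCMG-TBLC replicate 2 and mESC replicate 3), Sox1 no longer passed, at -0.53 on the log2 scale.

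Of 27 trophectoderm genes, 16 fell and 4 rose (17 and 4 adjusted over the list alone), with a median log2 fold change of -1.22. Gata3, a transcription factor of trophectoderm, fell 9.03-fold, from 2.80 ± 1.09 to 0.312 ± 0.133 CPM, Tfap2c fell 6.17-fold, Tfap2a 5.08-fold and Wnt7b 11.9-fold. Without mCMG-TBLC replicate 1 the log2 fold change of Wnt7b was -4.21, beside -3.58 with it. Cdx2 was at 0.278 ± 0.0578 against 0.666 ± 0.721 CPM and did not pass (edgeR adjusted p = 0.144), but passed as lower without mESC replicate 3, at -1.86 on the log2 scale, and without the 2 libraries in doubt, at -2.03. Without mESC replicate 2 it was at -0.14 and did not pass. Camera called the trophectoderm list lower (adjusted p = 0.0133, and adjusted p = 0.417 with an estimated correlation) and the polar trophectoderm list of 11 genes as well, with 7 lower, 2 higher and a median of -1.08 (adjusted p = 0.00739, and adjusted p = 0.421 with an estimated correlation). Of the polar members, Fgfr2 fell 3.52-fold. The mural list of 13 genes had 4 higher and 4 lower (4 and 5 adjusted over the list alone), was not called (camera adjusted p = 0.998), and had a median of -0.19 beside a mean of 0.01. Its members Aqp3 and Slc2a3 rose 5.27-fold and 2.57-fold, and Basp1 fell 2.16-fold. Of 25 primitive endoderm genes, 9 rose and 4 fell, with a median of 0.34 and no call (camera adjusted p = 0.0798). It was called without mCMG-TBLC replicate 3 (median 0.69), without the low-count filter (0.64) and after the trend over length and GC content was taken off (0.41 centred, 0.22 uncentred). P4ha2 (11.5-fold), Pdgfra (3.89-fold) and Col4a2 (3.02-fold) rose, and so did 24 of 29 fibroblast genes, with Col1a1 10.0-fold higher. Gata6 was at 6.05 ± 2.56 against 4.80 ± 1.36 CPM and did not pass (edgeR adjusted p = 0.398), though it passed without mCMG-TBLC replicate 3 at 0.69 on the log2 scale. Sox17 was at 1.37 ± 0.485 against 0.784 ± 0.343 CPM (edgeR adjusted p = 0.126).

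Fibroblast genes, which feeder cells express, were higher in mCMG-TBLCs. Of 29 members tested, 24 rose and 1 (Twist1) fell, with a median log2 fold change of 3.84 (the same with genes at 0 in a group set to their bound), and of 3.21 without the 2 libraries in doubt. Postn, an extracellular matrix gene, had no counts in mESCs and was at least 280-fold higher, or 163-fold without mESC replicate 2, at 14.3 ± 4.57 CPM. Col1a1 was at 32.3 ± 10.9 CPM against 3.15 ± 0.757 CPM. Col6a3 was at 13.1 ± 1.07 CPM against 0.0787 ± 0.0772 CPM, a log2 fold change of 7.201 that was 7.92 without mESC replicate 1. Cdh11 was at 6.30 ± 2.65 CPM in mCMG-TBLCs and had 1 count in mESCs, with a ratio of pooled counts of 366 (65.5 to 14480). That ratio was 213.6 without mESC replicate 2, and without mESC replicate 1, which held the single count, Cdh11 was at least 82.4-fold higher. Camera called the list (adjusted p = 2.83e-13, and adjusted p = 0.208 with an estimated correlation).

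DNA methylation and imprinting genes were mostly lower. Dnmt3b went from 241 ± 69.0 CPM in mESCs to 70.5 ± 12.2 CPM in mCMG-TBLCs (log2 fold change -1.78 ± 0.20, edgeR adjusted p = 3.18e-05), Dnmt3l fell 1.76-fold, and the demethylation genes Tet1 and Tet3 fell 2.24-fold and 2.26-fold. Of 10 members, 6 fell and 2 rose, with a median of -0.39 and no call for the list (camera adjusted p = 0.212). Among 25 imprinted genes, 14 fell and 3 rose, with a median of -0.82. Peg10 fell 3.81-fold, Mirg 3.31-fold and Kcnq1ot1, a long noncoding RNA antisense to Kcnq1, 3.87-fold. Camera called the imprinted list lower (adjusted p = 0.00739, and adjusted p = 0.417 with an estimated correlation). One of the 3 risers, Dcn, is also a fibroblast gene.

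Genes of the spliceosome, which PlaB inhibits, went both ways. Of 62 spliceosome genes, 18 rose, 24 fell and 20 did not pass, with a median log2 fold change of -0.07 and no call (camera adjusted p = 0.467). With the uncentred trend over length and GC content taken off, 13 were higher and 32 lower, with a median of -0.25 and still no call. The core small ribonucleoprotein genes Snrpg and Snrpd2 rose 3.34-fold and 2.93-fold, and Sf3a1 fell 2.57-fold. Sf3b1, which encodes the target of PlaB, was at 787 ± 26.6 against 904 ± 134 CPM and did not pass (edgeR adjusted p = 0.104). It was called higher, at 0.23 on the log2 scale, with the centred trend over length and GC content taken off. Of 36 p53 target genes, 12 rose and 15 fell, with a median of -0.13 and no call (camera adjusted p = 0.905). Cdkn1a, a cell cycle inhibitor, rose 2.10-fold to 117 ± 22.3 CPM and the cell death gene Pmaip1 6.01-fold. Bbc3, another cell death gene, fell 2.90-fold and Trp73 2.93-fold. Without mCMG-TBLC replicate 1 the log2 fold change of Trp73 was -2.21, beside -1.55 with it. Mdm2, which targets p53 for degradation, fell 1.40-fold and did not pass without mESC replicate 1 (log2 fold change -0.42).

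Ribosomal protein and glycolysis genes rose. Of 76 cytosolic ribosomal protein genes, 66 rose and 3 (Rpl18a, Rps6 and Rps26) fell, with a median log2 fold change of 0.98. Rps21 rose 6.06-fold, Rps29 5.46-fold and Rpl34 4.66-fold. These genes are short and have many processed pseudogenes, so their counts are uncertain, and the median was 0.62 with the centred and 0.43 with the uncentred trend over length and GC content taken off. Camera called the list (adjusted p = 2.29e-33, and adjusted p = 0.340 with an estimated correlation). Of 23 glycolysis genes, 19 rose and 2 (Pgam1 and Bnip3) fell (20 and 3 adjusted over the list alone), with a median of 0.54. The lactate transporter gene Slc16a3 rose 3.26-fold, Pfkfb4 3.001-fold and Aldoc 2.58-fold. Camera called the list (adjusted p = 0.00023, and adjusted p = 0.340 with an estimated correlation).

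Mitochondrially encoded and Y-linked transcripts fell. Of 13 mitochondrial genes, 11 fell and none rose, with a median log2 fold change of -1.81. mt-Atp6 was at 121 ± 35.8 against 2979 ± 238.5 CPM, and mt-Co2 and mt-Co3 fell 13.1-fold and 7.41-fold. Nuclear copies share these reads, so single genes are uncertain, and all mitochondrial genes and 3 abundant nuclear copies together were at 49140 ± 3372 against 156500 ± 16700 CPM, 3.19-fold lower. Mitochondrial genes took 3.75% ± 0.239 of counts in mCMG-TBLCs and 10.8% ± 0.980 in mESCs. Camera called the list lower (adjusted p = 1.56e-15, and adjusted p = 0.208 with an estimated correlation). Of 7 genes that report on the sex chromosomes, 5 fell and none rose, with a median of -2.25, or -1.64 with the centred trend over length and GC content taken off. Uty was at 1.65 ± 0.326 CPM in mCMG-TBLCs and 51.7 ± 5.30 CPM in mESCs, and Ddx3y at 4.53 ± 0.562 and 96.0 ± 7.55 CPM. Tsix, antisense to Xist, fell 5.40-fold, and reads of that pair cannot be told apart without strand. Camera called the list lower (adjusted p = 4.27e-10, and adjusted p = 0.0674 with an estimated correlation).

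Of 39 mitosis genes, 18 fell and 8 rose (19 and 8 adjusted over the list alone), with a median log2 fold change of -0.16. Ube2c fell 2.15-fold, Nusap1 2.15-fold and Ckap2l 2.16-fold. Camera called it lower (adjusted p = 0.0232, and adjusted p = 0.340 with an estimated correlation). The call was also lost with upper-quartile scaling (median -0.08), with a 1 CPM filter (-0.13) and with the centred trend over length and GC content taken off (-0.12). Of 36 DNA replication genes, 11 rose and 9 fell (median 0.07, camera adjusted p = 0.652), among them Rpa1 (2.10-fold up), Rpa2 (1.96-fold up) and Fen1 (1.90-fold up). Of 33 replication-dependent histone genes, 19 rose and 3 fell (median 1.38, camera adjusted p = 0.0664). Hist1h4i rose 11.1-fold. Hist1h2bc fell 1.36-fold but did not pass without mCMG-TBLC replicate 1 (log2 fold change -0.34) or 3 (-0.37), without mESC replicate 1 (-0.41) or 2 (-0.40), with upper-quartile scaling (-0.37) or without the low-count filter (-0.40). The histone list was called without mCMG-TBLC replicate 1 (median 1.41) and without the low-count filter (1.48), and its median was 0.49 with the 1 CPM filter, where it was not called. These transcripts mostly lack poly(A) tails, so their counts depend on the library type. The integrated stress and unfolded protein list had 5 of 25 members higher and 6 lower (median -0.04 beside a mean of 0.03, camera adjusted p = 0.905). Its member Ddr2, a collagen receptor also found on fibroblasts, rose 12.6-fold beside the fibroblast genes, and Cebpb and Nupr1 fell 3.98-fold and 3.63-fold. Without mESC replicate 3, where Nupr1 was at 28.5 CPM beside 8.59 and 8.22 CPM in the other mESC libraries, its log2 fold change was -1.04 in place of -1.86. Cholesterol synthesis had 7 of 23 higher and 8 lower (median -0.02 beside a mean of 0.07, camera adjusted p = 0.905), with Tm7sf2 up 2.34-fold, Ebp up 2.17-fold and Pmvk up 1.70-fold. Immediate early genes had 6 of 19 higher and 7 lower (median 0.09, camera adjusted p = 0.746), with Fosb up 11.6-fold, Fos up 7.28-fold and Jun up 3.63-fold. The interferon and double-stranded RNA list had 5 of 13 higher and 1 lower (median 0.40, camera adjusted p = 0.652), with Bst2 up 2.08-fold, Stat2 up 1.55-fold and Ddx58 down 1.76-fold. Bst2 did not pass with the uncentred trend taken off (log2 fold change 0.41).

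**Figure D2:**
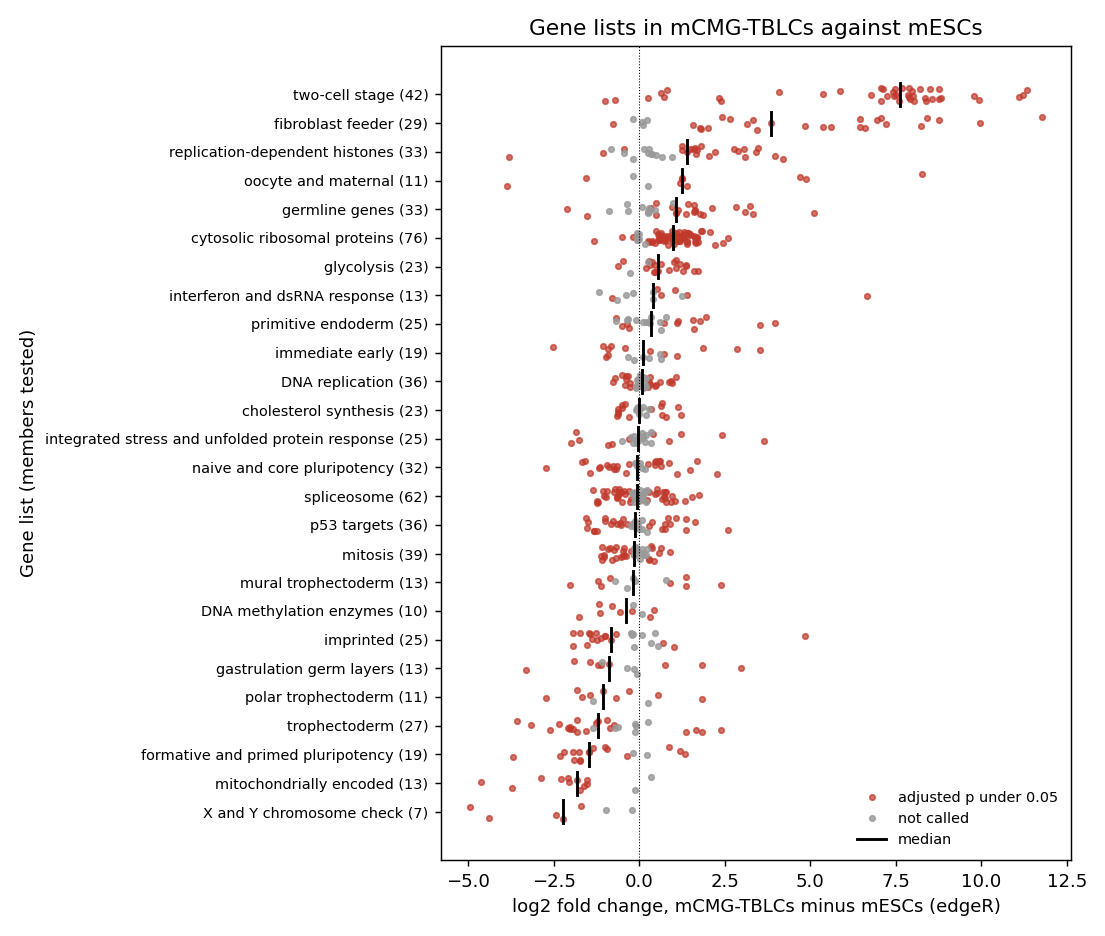
Log2 fold change (mCMG-TBLCs minus mESCs, horizontal axis) of each tested member of the 26 gene lists, as fitted by edgeR. Points are genes (red, adjusted p under 0.05; grey, not called), black lines are medians, and numbers in brackets are members tested. Fitted values of genes at 0 in a group depend on the prior count. The two-cell stage list has the highest median (7.63) and the sex chromosome list the lowest (-2.25).

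The genes with the largest changes under the rule for named genes also included Spz1, a testis transcription factor with no counts in mESCs and 5.29 ± 1.20 CPM in mCMG-TBLCs, at least 104-fold higher, or 60.4-fold without mESC replicate 2. The largest falls were those of Asdurf, Insm1, Uty, mt-Atp6, Ddx3y and Kctd12b. Asdurf (chromosome 1, 53348479 to 53352619, mm10) was at 7.16 ± 0.889 CPM in mESCs and at 0 in mCMG-TBLCs, at least 301-fold lower, or 196.5-fold without mCMG-TBLC replicate 3. It lies within Asnsd1, which was at 75.1 ± 9.05 CPM in mESCs and 100.4 ± 8.53 CPM in mCMG-TBLCs and was picked after its values were seen, so the split of reads between them is uncertain. Insm1, a zinc finger gene of neuroendocrine cells, fell 35.5-fold from 13.1 ± 3.37 CPM, and Kctd12b fell 17.3-fold from 5.06 ± 3.04 CPM. The log2 fold change of Insm1 was -5.15, and -5.77 without mCMG-TBLC replicate 1.

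Since PlaB acts on splicing, fold changes were set against the number of exons. Genes with more exons had slightly lower fold changes: over 16255 genes Spearman's rho was -0.097, and it ranged from -0.126 to -0.0501 over the 9 contrasts of single libraries. This is a correlation across genes, which are not independent replicates. The correlation with exon length was -0.18. The median log2 fold change was 0.19 for 1483 single-exon genes and 0.04 for multi-exon genes. Restricted to protein-coding genes, multi-exon genes lay below single-exon genes by -0.21, in 9 of 9 contrasts. Restricted further to those above 5 CPM, with 150 single-exon genes, multi-exon genes lay above by 0.18, also in 9 of 9 contrasts. Among genes of all types above 5 CPM, with 337 single-exon genes, the difference was -0.07, with multi-exon genes below in 8 of 9 contrasts.

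The single-cell libraries showed which cell classes TBLC-blastoids held. Of 2788 cells clustered, 1192 were epiblast-like (42.8%, 95% interval 40.9 to 44.6) and 1026 trophectoderm-like (36.8%, 35.0 to 38.6). A further 93 were primitive endoderm-like (3.34%, 2.70 to 4.07). These 3 classes were named from markers of the 3 lineages of a blastocyst, which does not show that they match those lineages. Another 40 cells were two-cell-like (1.44%, 1.03 to 1.95) and 9 were blood-like (0.323%, 0.148 to 0.612), and 428 cells in 2 clusters had no name (15.3%, 14.03 to 16.7). Intervals are exact binomial and cover counting error only. The table pools both libraries and no label ties a cell to a library, so it counts as 1 sample and no test was made. The 2 barcode suffixes may or may not be the 2 libraries. Epiblast-like cells were 47.5% (44.8 to 50.3) of suffix 0 and 38.8% (36.4 to 41.3) of suffix 1. Primitive endoderm-like cells were 4.13% (3.10 to 5.38) and 2.68% (1.93 to 3.62). Suffix shares of the trophectoderm-like class are given by cluster. The 10 leading genes of cluster 7 held 1 spongiotrophoblast marker (Cdkn1c) and no trophectoderm marker. Cluster 2 made up 13.7% (11.9 to 15.8) and 23.6% (21.5 to 25.8) of the 2 suffixes, cluster 4 8.18% (6.72 to 9.83) and 12.2% (10.6 to 13.9), and cluster 7 5.48% (4.29 to 6.88) and 8.77% (7.40 to 10.3). Without cluster 7 the class was 29.5% of all cells. The share rests on the naming rule: it was 10.4% when names came from the top 30 genes against the mean of other clusters, and 0.0% from the top 10 genes. From the top 10 genes, or with 4000 variable genes, no cells were named two-cell-like, and with 15 principal components none blood-like.

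**Figure D3:**
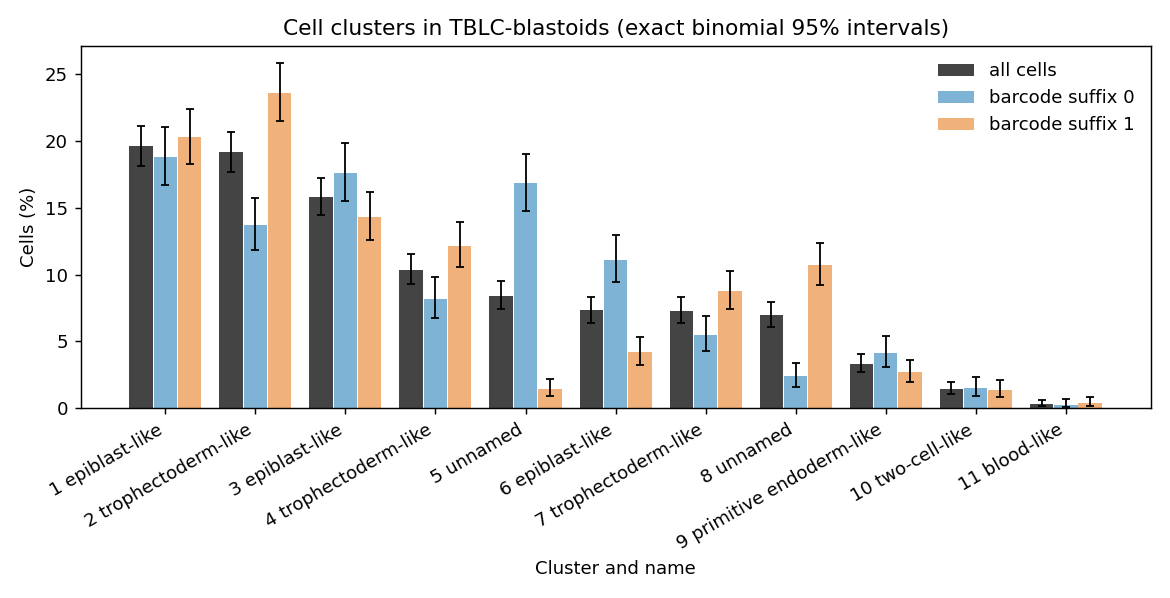
Share of cells in each cluster (vertical axis, percent; horizontal axis, cluster number and name) for all 2788 cells and for each barcode suffix. Bars are shares and error bars are exact binomial 95% intervals, which cover counting error only. Cluster 2 makes up 13.7% and 23.6% of the cells of the 2 suffixes, and cluster 5 16.8% and 1.44%.

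The epiblast-like class was made of clusters 1, 3 and 6, with 11 to 13 epiblast markers each. Tdgf1, Nanog, Zfp42, Sox2 and Klf2 were among the 10 leading genes of each. Tdgf1 stood first in clusters 1 and 3, and Dppa3 in cluster 6. Clusters 2, 4 and 7 formed the trophectoderm-like class with 6 to 8 markers, led by Rhox9, Rhox6, Cdkn1c and Nrk in clusters 2 and 7 and by Wnt5a, Cxcl12 and Tacstd2 in cluster 4. Among the 10 leading genes, clusters 2 and 4 had 1 trophectoderm marker each (Plac1 and Krt7) beside 1 marker of another class, and cluster 7 had none beside Cdkn1c of spongiotrophoblast. Cluster 9, primitive endoderm-like, was led by Col4a1, Cited1, Col4a2, Lama1 and Dab2, with 17 markers. Cluster 10, two-cell-like, was led by predicted genes with Platr31 and Fbxo15. It had 5 markers (Sp110, Usp17lc, Zscan4c, Arg2 and Zscan4d), none of them among its 10 leading genes. Of those leading genes, Gm21761, Gm8300, Gm5662, Gm5039 and Gm20767 belong to the two-cell stage list. That list was left out of clustering and took 73.9 UMIs per 10000 in cluster 10, against 8.15 in epiblast-like cells. It shares genes with the markers that gave the name, so it is no separate test of it. Cluster 11, blood-like, was led by the globin genes Hba-x, Hbb-bh1 and Hbb-y.

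The lineage factors split by class, although they also served to name the classes. The trophectoderm-like values in this comparison include the 203 cells of cluster 7. Pou5f1 had a UMI in 98.8% of epiblast-like cells and in 18.2% of trophectoderm-like cells (median depths 50771 and 56490 UMIs), and Nanog in 96.7% and 10.9%. Sox2 was at 5.26 UMIs per 10000 in epiblast-like and 0.1002 in trophectoderm-like cells. Gata3 had a UMI in 81.7% of trophectoderm-like cells, 10.7% of epiblast-like cells and none of the 93 primitive endoderm-like cells. For this last class, the exact binomial interval allows a share of cells with a UMI of up to 3.89%. Cdx2 was seen in 19.3% of trophectoderm-like cells (16.9 to 21.9) and 2.94% of epiblast-like cells, with 168 of the 198 trophectoderm-like cells in cluster 4, and in 29.0% of primitive endoderm-like cells, at 0.2024, 0.0121 and 0.0837 UMIs per 10000. Krt8, a keratin of trophectoderm, was at 16.3 UMIs per 10000 in trophectoderm-like and 0.170 in epiblast-like cells, though 53.4% of the latter had a UMI. Gata4 and Sox17 had a UMI in all 93 primitive endoderm-like cells and Gata6 in 95.7%, against 2.94%, 4.11% and 7.13% of epiblast-like cells (median depth 43205 UMIs in primitive endoderm-like cells). Zscan4c had a UMI in 52.5% of two-cell-like cells (36.1 to 68.5) and 0.587% of epiblast-like cells, and Zfp352 in 17.5% and 0.252%, at median depths of 31245 and 50771 UMIs. Col1a1, a fibroblast collagen, had a UMI in 1.43% of epiblast-like, 0.780% of trophectoderm-like and 12.6% of unnamed cells.

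**Figure D4:**
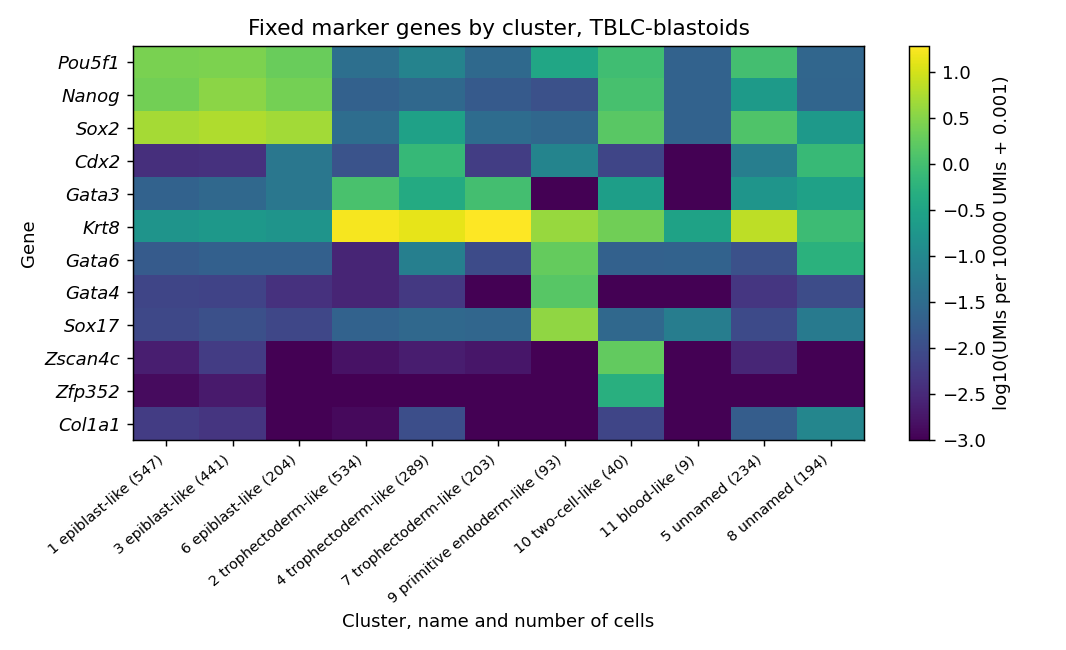
Level of 12 marker genes fixed in advance (rows) in the 11 clusters of TBLC-blastoid cells (columns, with the name and number of cells). Colour is log10 of UMIs per 10000 UMIs plus 0.001. Pou5f1, Nanog and Sox2 are highest in clusters 1, 3 and 6, Krt8 in clusters 2, 4 and 7, Gata4 and Sox17 in cluster 9, and Zscan4c in cluster 10.

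Gene lists that were left out of clustering differed between the 3 lineage classes. Cholesterol synthesis genes took 16.9 UMIs per 10000 in primitive endoderm-like cells (exact Poisson 95% interval 16.5 to 17.2), 11.1 in trophectoderm-like (10.99 to 11.2) and 6.65 in epiblast-like cells (6.59 to 6.71), and stood in this order in both barcode suffixes. Integrated stress and unfolded protein genes were at 31.0 (30.5 to 31.5) in primitive endoderm-like cells. They were at 22.9 (22.8 to 23.0) in epiblast-like and 20.9 (20.8 to 21.0) in trophectoderm-like cells. This last pair stood at 21.5 and 21.6 in barcode suffix 0 (21.5 and 21.1 without cluster 7). The endoplasmic reticulum chaperone genes Hsp90b1 and Hspa5 were at 11.2 and 10.0 in primitive endoderm-like cells. In epiblast-like cells they were at 5.17 and 4.37, and in trophectoderm-like cells at 5.15 and 5.57. Without these genes, the rest of the list together was lower in primitive endoderm-like than in epiblast-like cells. The list was therefore not higher as a whole. Ribosomal protein genes took 3106 UMIs per 10000 in epiblast-like (3105 to 3107), 2370 in trophectoderm-like (2369 to 2371) and 2241 in primitive endoderm-like cells (2237 to 2246). In suffixes 0 and 1 they were at 3136 and 3061, 2291 and 2420, and 2131 and 2356.5 in these classes. The order held within each suffix, but trophectoderm-like and primitive endoderm-like values overlapped across suffixes. DNA replication genes were at 31.3 (31.1 to 31.4), 24.6 (24.5 to 24.7) and 19.3 (18.9 to 19.7) in the same order of classes. Spliceosome genes were at 128.9 (128.6 to 129.1), 109.6 (109.3 to 109.8) and 108.4 (107.5 to 109.4), with trophectoderm-like below primitive endoderm-like cells in suffix 1 (106.4 and 106.7, but 109.5 and 106.7 without cluster 7), and glycolysis genes at 124.7 (124.5 to 125.0), 112.6 (112.4 to 112.9) and 97.4 (96.5 to 98.3). Mitosis genes were at 42.2 (42.0 to 42.3), 40.03 (39.9 to 40.2) and 35.2 (34.6 to 35.7), but epiblast-like cells were above trophectoderm-like cells in barcode suffix 1 only (46.0 and 35.9, against 39.6 and 46.5 in suffix 0), and without cluster 7 trophectoderm-like cells stood above them, at 42.9. p53 targets were at 32.9 (32.8 to 33.1) in epiblast-like, 20.3 (20.2 to 20.4) in trophectoderm-like and 29.4 (28.9 to 29.9) in primitive endoderm-like cells, with the first and last at 33.35 and 33.40 in suffix 1 and with Rps27l taking 34.4%, 26.7% and 35.0% of these. Two-cell stage genes were at 8.15 (8.08 to 8.22), 3.24 (3.20 to 3.29) and 2.06 (1.93 to 2.20), but Kdm5b alone made up 79.9%, 76.3% and 70.2%, and without it the sums were 1.64, 0.768 and 0.616.

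Some cells held markers of more than 1 lineage. At 1 UMI or more, 868 of 2788 cells (31.1%, 29.4 to 32.9) had markers of 2 or more of epiblast (Pou5f1 or Nanog), trophectoderm (Cdx2 or Gata3) and primitive endoderm (Gata6 or Sox17), where independent detection gives 39.7%, with 31.8% and 30.6% in the 2 barcode suffixes. Epiblast and trophectoderm markers met in 19.4% of cells (30.8% by independence), epiblast and primitive endoderm markers in 8.93% (11.2%), and trophectoderm and primitive endoderm markers in 9.29% (8.53%). All 3 lineages were found in 3.23% of cells (5.43%). The share with 2 or more lineages was 9.47% (23.8% by independence) when 2 UMIs were required, and 14.1% (26.4%) when each cell was thinned to 20000 UMIs, which left out 35 cells of barcode suffix 0 and 115 of suffix 1. Single UMIs in droplets can come from free RNA, and Nanog had a UMI in 10.9% of trophectoderm-like cells.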

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

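The loess trend over length and GC content, the fit without 2 libraries in doubt and the 4 other forms of naming were chosen only after the results were seen. The count of 9780 changed genes stayed within 1.5 times (8332 to 10412) under every alternative but the test against a 1.5-fold change, which gave 4765 because of its stricter hypothesis. Leaving out each library gave 8332 to 10232 genes, leaving out the 2 libraries in doubt 8884, DESeq2 9826 and limma-voom 9703. The replicate number as a block gave 9557 genes. Same-numbered libraries deviated together with correlations of only 0.017 to 0.0605, none above 0.1. With 3 such pairs, this shows no clear pairing by number but cannot exclude it. Of the 10 splits of the 6 libraries, 1 gave as many genes as the real one (the real split itself, 9780), and the highest other split gave 0 by edgeR (21 to 336 genes at an unadjusted p under 0.05, other tools not run), too few splits for a share under 0.05. The trend over length and GC content gave 9661 genes (5208 higher, 4453 lower) when centred and 9849 when not (4034 higher, 5815 lower, a median shift of -0.17). The centred form was chosen after the uncentred one had been seen, and 39 and 79 genes changed sign between calls.

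Camera called 12 lists, 12 to 13 when a library was left out, 11 to 14 under the other scalings, filters and trends, and 0 with an estimated correlation, and fry called 17. The cause of the loss was not tested. For the sex chromosome list the estimated correlation was -0.0504, below the preset 0.01, so a higher correlation does not account for the loss there. The other called lists had estimated correlations above the preset, from 0.0221 (mitosis) to 0.563 (cytosolic ribosomal proteins). Of 98 named genes, 83 kept their call under every alternative, and the reversals were Zfp42 at -0.47 with the centred and -0.65 with the uncentred trend, and Sf3b1 at 0.23 with the centred trend. Neither passed in edgeR with TMM factors and no trend, Zfp42 passed at 0.16 with upper-quartile factors, and the cause was not tested. The centred trend moved some values by over 1.5 times with the call kept, to -4.67 for Dppa3, -4.29 for Uty, -3.79 for Ddx3y, -1.17 for Hist1h2bc, -1.14 for Kcnq1ot1, 1.11 for Snrpg, 1.77 for Rps21, 1.56 for Rps29, 2.75 for Hist1h4i and 9.30 for Usp17lb on the log2 scale. Rho with exon number ranged from -0.125 (without mESC replicate 3) to -0.0808 when a library was left out.

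The epiblast-like share was 49.3% at resolution 1.0, 49.6% with 1000 variable genes, 49.4% with the stricter cell filter, 51.2% with seed 2 and 51.1% with names from the top 100 genes, in the last case because cluster 5 then joined it. With seed 1 the epiblast-like share was 42.5%, beside 42.8% in the main clustering. The trophectoderm-like share was 45.3% at resolution 0.3, 38.7% with the stricter filter, 29.3% with a per-cell score (701 cells lay within 0.1 of the next class), 29.5% without cluster 7, 10.4% with names from the top 30 genes against the mean and 0.0% from the top 10 genes, where fewer genes were searched. The unnamed share, 15.3% in the main clustering, was 6.77% with the stricter filter, 6.85% at resolution 0.3 and at 1.0, and 7.14% with 1000 variable genes. With names from the top 30 genes against the mean it was 33.4%, and from the top 10 genes 53.6%. The cause of the other shifts was not tested. The primitive endoderm-like share stayed within its interval under all of these. Two-cell-like cells were not named with 4000 variable genes, nor blood-like cells with 15 components. With the per-cell score the two-cell-like share was 0.717%, beside 1.44% in the main clustering. With doublets kept, trophectoderm-like sums were 113.0 (glycolysis), 24.4 (DNA replication), 39.5 (mitosis) and 2378.0 (ribosomal) per 10000. Without cluster 7, whose 10 leading genes held more markers of another class, they were 111.8 (glycolysis), 26.4 (DNA replication), 42.9 (mitosis), 2385 (ribosomal), 3.19 (two-cell stage), 20.1 (p53 targets), 112.7 (spliceosome), 20.06 (stress) and 10.7 (cholesterol synthesis), with its cells left out of the sums. Cells with 2 or more lineages were 9.47% at 2 UMIs and 14.1% after thinning, so this share depends on the UMI threshold and on depth. Leaving out each single-cell library, and RLE factors, no filter and camera with an estimated correlation for single-cell sums, were not run. No cell filter equals the filter used, which removed 0 cells.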

Other observations

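The tests of chromosome 14 and the test of missed detection of Y-linked UMIs were chosen only after the results were seen. The share of cells with Y-linked UMIs, in all cells and by cluster, had been seen before the other Y-linked test was written.

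Cells without a name formed 2 clusters of different makeup. Cluster 5 (234 cells, 212 of them in barcode suffix 0) held epiblast and formative transcripts next to keratins. Per 10000 UMIs it had 1.02 of Pou5f1 (2.52 in epiblast-like cells), 1.08 of the formative epiblast gene Pou3f1 (0.0341 in epiblast-like and 0.268 in trophectoderm-like cells), 0.778 of Otx2 (0.448 in epiblast-like cells) and 10.38 of Krt18 (24.9 in trophectoderm-like and 0.368 in epiblast-like cells). It had 4 markers of epiblast and 4 of formative or primed epiblast. Cluster 8 (194 cells, 164 of them in suffix 1) was led by 2610528A11Rik, Dlk1, Tgfb2 and Twist1. Markers of extraembryonic ectoderm and of fibroblasts or feeder cells tied in it, with 2 each. Col3a1 had a UMI in 28.9% of its cells (0.245 per 10000 UMIs, at most 0.00283 in any other cluster) and Col1a1 in 19.07% (0.0902, at most 0.0172), whereas Col1a2 was at 0.0351 beside 0.0347 in cluster 4. Per 10000 UMIs it had 2.98 of Dlk1, 2.27 of Twist1, 2.35 of Msx1, 0.724 of the posterior patterning gene Hoxa9, 0.533 of Gata6 and 0.758 of Cdx2, against 0.0105, 0.0171, 0.0143, 0.00314, 0.0177 and 0.0121 in epiblast-like cells. Gata6 and Cdx2 do not set cluster 8 apart. Gata6 was at 1.85 in primitive endoderm-like cells, and Cdx2 was also a marker of cluster 4. Each cluster lies mostly in 1 barcode suffix, so either could be a feature of that set of cells, and the epiblast-like share with names from the top 100 genes (51.1%) includes cluster 5. All genes in these sentences but Pou5f1, Gata6, Cdx2 and Col1a1 were picked after their values were seen.

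Genes of chromosome 14 were higher in mCMG-TBLCs as a group. Their median log2 fold change was 0.57 over 354 protein-coding genes above 5 CPM (1.48-fold, where 3 copies against 2 give 1.5-fold), while medians of the other autosomes lay between -0.21 and 0.13, and chromosome 14 was the highest in 9 of 9 contrasts of single libraries. Against a few clusters of changed neighbours, the median was still 0.423 without the 5 blocks of 20 neighbouring genes with the highest medians, and against length or GC content it was 0.679 after the trend was taken off, where the highest other autosome had 0.24. An extra copy of chromosome 14 in mCMG-TBLCs is a candidate explanation, since 100% of its 18 blocks lay above the autosomal median. At most 75% did on any other autosome. The block medians were uneven, from 0.146 to 1.40 on the log2 scale, where 3 copies against 2 give 0.585. An extra copy stays a hypothesis from RNA alone. A difference between the parental lines cannot be separated in it from one that arose in culture.

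The fibroblast list was higher in mCMG-TBLCs, and a different share of feeder cells in the libraries may account for it. Its median was 3.84 on the log2 scale, 3.05 to 4.58 over the 9 contrasts, and all 6 abundant fibroblast transcripts lay above 0. Of these, Col1a2 was at 33.0 ± 6.98 CPM against 0.322 ± 0.1495 CPM and Col3a1 at 17.3 ± 2.50 against 0.152 ± 0.104 CPM, whereas Fn1, which mESCs express at 1331 ± 34.1 CPM, was at 1413 ± 174 CPM and did not pass. Twist1 went the other way. All of the 6 abundant transcripts but Sparc are also members of the list itself. Expression of these genes by the blastomere-like cells themselves was not tested and stays open. It would raise the same transcripts, so their shared rise cannot tell it from a different share of feeder cells.

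Y-linked UMIs were found in some TBLC-blastoid cells and not in others. At least 1 UMI of Eif2s3y, Ddx3y, Uty or Kdm5d was found in 51.8% of cells (49.9 to 53.6), in 52.3% and 51.3% of the 2 barcode suffixes and in 40.9% to 66.7% of cells of each class. The tables argue against missed detection at this depth, as 51.4% of cells had no UMI of Eif2s3y while 536 genes of the same mean count had a median of 21.0% and a 95th percentile of 43.7%. Loss of the Y chromosome from some of the cells may be a cause, but the test was not decisive: another Y-linked gene had a UMI in 6.21% of cells without Eif2s3y and 29.6% of cells with it, a relative share of 21.0% where under 20% had been set. In the bulk mCMG-TBLC libraries, Uty was at 1.65 CPM and Ddx3y at 4.53 CPM, against 51.7 and 96.0 CPM in mESCs. Y-linked transcripts were thus low in bulk mCMG-TBLCs, while 51.8% of TBLC-blastoid cells had a Y-linked UMI. How these 2 sets of cells relate was not tested. A mixture of cells of different origin was not tested, and the design names no biological explanation. Whether free RNA adds to the lower share stays open.

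A lower output of multi-exon genes under the splicing inhibitor was tested as a hypothesis. Among protein-coding genes above 5 CPM, multi-exon genes were predicted to lie below single-exon genes in all 9 contrasts of single libraries, and they did so in 0 of 9, although rho was -0.0861. Without the 5 CPM limit they did so in 9 of 9, and among genes of all types above 5 CPM in 8 of 9, so the direction differed with the set of genes taken.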
